A study of Mus musculus with 228 samples.

How the data were processed

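RNA of single neurons, taken by patch pipette from mouse hippocampal slices, was sequenced in 4 groups, EGFP GC, Ascl4 GC, EGFP CA1 and Ascl4 CA1. The deposited tables hold read counts per gene, 1 with all 228 cells and 1 with the 189 cells kept by the authors' quality control, and the counts of the shared cells are identical in both. A further deposited table holds normalized signal for the 189 cells, in which the authors divided the counts by 1 factor per cell (the ratio of signal to count had a coefficient of variation of at most 2.6e-16 within a cell). The method behind these factors and the rules of the quality control are not given in the sources used here. Per the labels, reads were processed with STAR and HTSeq on GRCm38.p4, whose versions and settings are not given in the sources used here. The series text states 53, 52, 48 and 51 cells past quality control (204 in all) for EGFP GC, Ascl4 GC, EGFP CA1 and Ascl4 CA1, whereas the table holds 47, 51, 46 and 45, and the table was used. Besides 22870 gene rows there were 92 spike-in rows, which held 5 reads and were left out of totals.

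The labels name no animal, culture or batch. The cells of a group were therefore not treated as replicates, each group counted as 1 sample, and no test or p-value was computed. Groups came from the cell titles. The comparisons were Ascl4 against EGFP in GC, Ascl4 against EGFP in CA1, and EGFP CA1 against EGFP GC. Reads of all cells of a group were summed, scaled to a total of 1000000 (CPM) and compared as the log2 ratio of CPM with a pseudocount of 1. Deeper cells weigh more in such sums. Genes counted as expressed when at least 25% of the cells of 1 group had a read and the pooled value was at least 10 CPM in 1 group. Intervals were exact Poisson (counts) or exact Clopper-Pearson (shares of cells) at 95%.

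The 25 gene lists (961 genes, of which 960 were found by symbol) cover cell type markers, neuronal and wiring genes, and stress, immune and housekeeping genes. For each list the median log2 ratio of expressed members was placed as a percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. Lists in the outer 2.5% on either side were called, lists with fewer than 5 expressed members got no value, and members at least 1.5-fold higher or lower were counted. A percentile places a list among other genes of the same summed reads. It treats genes as independent and does not measure the spread between cells or animals. No adjustment was made for the number of lists. Some genes are on more than 1 list. For the comparison of cell labels, the summed CPM of the granule cell list was set against that of the CA1 list in each cell. Detected genes were counted as deposited and after thinning each cell to 500000 reads.

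Genes were named by a rule. It took, for each comparison, the 12 highest and 12 lowest expressed genes that differed at least 1.5-fold the same way in the summed reads, the mean of per-cell CPM and both runs of title numbers, and whose share of cells with a read differed the same way. Predicted gene models, pseudogenes, ribosomal protein genes and mitochondrially encoded genes were excluded. The rule also took a set of fixed genes, among them Ascl4, Prox1, Calb1, Neurod6, Wfs1, Slc17a7 and Gad1, up to 4 members of each list, and up to 10 genes that differed in both responses. Genes picked later are marked as such where they appear. The groups, comparisons, lists, naming rule and main alternatives were set before the data were examined. Leaving out cells with more than 12000 genes, leaving the gene CT010467.1 (1.6% of reads) and Ascl4 out of totals, and leaving the interferon and microglia lists out of the similarity were chosen after seeing the data.

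Alternatives tried were the mean of per-cell CPM, the same mean without the highest cell of each group for each gene, leaving out the deepest 10% of cells, pseudocounts of 0.1 and 10 CPM, edgeR TMM and DESeq2 median-of-ratios scaling, totals without mitochondrial genes, no expression filter or a stricter one (50% of cells and 50 CPM), all cells without quality control, the authors' normalized values, each number run alone and thinned cells. Positions of genes came from GENCODE annotation of GRCm38, matched by symbol for 22566 of 22870 genes. The code was tested on simulated data with known changes. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0. Raw reads were not used here.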

Results

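Gene expression was measured by RNA sequencing of single neurons drawn into a patch pipette from slices of mouse ventral hippocampus. Granule cells (GC) were reached through Calb1-Cre mice and pyramidal cells of medial CA1 (CA1) through Nex-Cre mice, so cell type and Cre line cannot be separated. The mice were 3 to 4 months old and had received adeno-associated virus (AAV) in the hippocampus 1 month earlier. Control cells carried a Cre-dependent AAV for the green fluorescent protein EGFP alone, and the other cells received that virus together with an AAV for Ascl4, a basic helix-loop-helix transcription factor of the achaete-scute family. No group received a second virus without Ascl4, so effects of Ascl4 and of a second virus cannot be separated. The authors' quality-controlled table held 47 EGFP GC, 51 Ascl4 GC, 46 EGFP CA1 and 45 Ascl4 CA1 cells. The labels give no animal, so each group counted as 1 sample, no test between groups was possible, and the spread between animals is unknown. Values below are counts of gene-assigned reads of a group, summed over its cells and scaled to a total of 1000000 (CPM). Log2 ratios were taken with 1 CPM added, which understates the fold of genes with low values. The title numbers of each group were parted into 2 runs, which the labels do not call batches, and values were recomputed in each run. The first and second run held 15 and 32 EGFP GC, 33 and 18 Ascl4 GC, 15 and 31 EGFP CA1, and 17 and 28 Ascl4 CA1 cells. A difference between runs therefore also enters the summed reads, above all in GC. Each run is unbroken apart from single missing numbers, except the second of Ascl4 CA1 cells, which joins 2 blocks with EGFP CA1 cells between them. Values without the highest cell are means of per-cell CPM with the highest cell of each group left out, and they are set against the same mean over all cells. The 95% exact Poisson intervals of CPM and the exact binomial intervals of shares of cells cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

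Total reads per cell ranged from 1077532 to 25442664. The summed reads were 215001259 in EGFP GC, 293049911 in Ascl4 GC, 249606719 in EGFP CA1 and 214178461 in Ascl4 CA1 cells. The median number of genes with a read was 6975 in EGFP GC, 6875 in Ascl4 GC, 6919 in EGFP CA1 and 6832 in Ascl4 CA1 cells. With every cell thinned to 500000 reads, the medians were 4292, 4041, 4420 and 4920 in the same order. In Ascl4 GC cells 4 cells, and in Ascl4 CA1 cells 1 cell, had more than 12000 genes with a read, with a maximum of 17883, and no EGFP cell did.

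The first comparison asked whether Ascl4 RNA was present in the cells that received its virus. Ascl4 (chromosome 10, 85927681 to 85946206, plus strand, GRCm38) stood at 14111 CPM (14097 to 14124) in Ascl4 GC cells and at 47.2 CPM (46.3 to 48.2) in EGFP GC cells, a ratio of 299. In CA1 cells it stood at 9395 CPM (9382 to 9408) with the Ascl4 virus and at 32.6 CPM (31.9 to 33.3) without it, a ratio of 289. Ascl4 reached 200 CPM in 50 of 51 Ascl4 GC and 44 of 45 Ascl4 CA1 cells, against 1 of 47 EGFP GC and 0 of 46 EGFP CA1 cells. At least 1 Ascl4 read was nonetheless found in every cell of all 4 groups. After thinning to 500000 reads it was found in 45 of 47 EGFP GC and 41 of 46 EGFP CA1 cells. The lowest Ascl4 CA1 cell held 23.2 CPM, within the range of the EGFP CA1 cells, whose highest held 153.2 CPM. Reads of the viral Ascl4 transcript and of the cells' own gene cannot be separated in these counts.

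**Figure D1:**
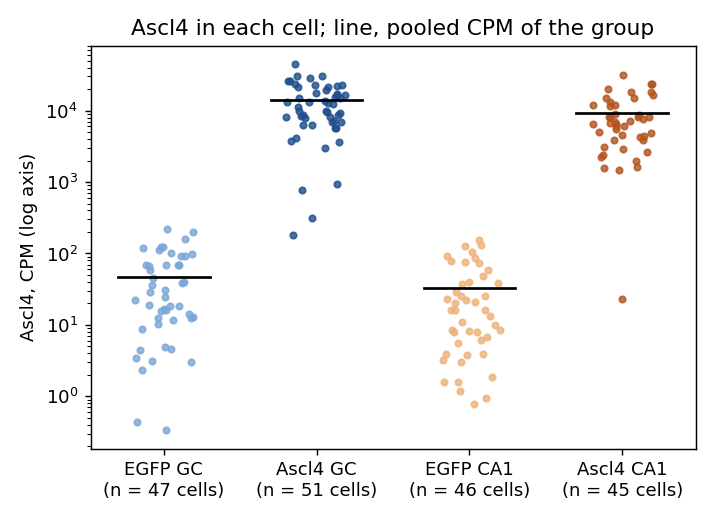
Ascl4 level of each cell (points, CPM on a log axis) in the 4 groups, with the CPM of the group's summed reads as a line. Single Ascl4 GC cells lay between 182.9 and 44534 CPM, and single EGFP GC cells between 0.33 and 221.7 CPM.

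The comparison of CA1 with GC cells among EGFP controls asked which genes set the 2 neuron types apart without the Ascl4 virus. The granule cell synaptic organizer C1ql2 was at 1017 CPM in GC and 0.18 CPM in CA1 cells (log2 ratio -9.75), and it reached 10 CPM in 38 of 47 and 0 of 46 cells. Prox1, the transcription factor that marks granule cells, was at 175.3 CPM (173.5 to 177.1) in GC and 0.24 CPM in CA1 cells. Neurod6, a transcription factor of pyramidal neurons, went the other way, with 0.11 CPM in GC and 319 CPM (317 to 322) in CA1 cells. The pyramidal genes Fibcd1, Sv2b and Cpne7 were also higher in CA1 cells, at 543, 331 and 1257 CPM against 3.21, 0.20 and 4.13 CPM. Gad1, which makes GABA, was at 449 CPM in granule cells and 17.3 CPM in CA1 cells. The chemokine Cxcl12 was at 128.3 CPM and the matrix protein gene Smoc2 at 121.9 CPM in GC cells, and they were at 0.02 and 0.03 CPM in CA1 cells. Without the highest cell the log2 ratio of mean CPM was 9.50 in place of 8.13 for Cpne7, 8.78 in place of 7.07 for Fibcd1 and -6.40 in place of -4.41 for Gad1. Other genes high in CA1 cells by the naming rule were Cpne8, Man1a, Runx1t1, Ptpru, Meis2, Lefty1, Ldb2 and Dcn, and others high in GC cells were Stxbp6, Dock10, Synpr, Sema5a, Kcnj2, Zfpm2, Capn3 and Napepld.

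Granule cell markers had a median log2 ratio of -4.27 between EGFP CA1 and GC cells, with 25 of 26 expressed members at least 1.5-fold lower in CA1. CA1 pyramidal markers had a median of 2.00, with 19 of 27 higher and 2 lower. Among random lists matched on expression, granule cell markers stayed at percentile 0.00 and CA1 markers at 99.99 or above under all 17 alternatives. The median of all genes was 0.02, and TMM scaling moved it to -0.09, median-of-ratios scaling to -0.09 and the authors' normalized values to -0.24. CA3 and mossy cell markers (1.34, percentile 99.97) and microglia markers (1.66, percentile 100) were higher in CA1 cells, the microglia list with 0.37 and percentile 87.4 in the cells of the second number run alone. Activity-regulated genes were lower in CA1 cells (-0.73, percentile 0.00), with Bdnf, a neurotrophin induced by activity, at 103.4 CPM against 509 CPM in GC cells, but their median in the second number run was -0.13 (percentile 34.6). Cadherins and protocadherins (-0.51, percentile 1.28) and progenitor genes (-1.28, percentile 0.65) were lower too. Glutamatergic and postsynaptic genes (0.34, percentile 97.9) were higher, and so were presynaptic release genes (0.31, percentile 99.4), voltage-gated channel genes (0.43, percentile 99.1) and interneuron markers (1.07, percentile 99.1). The presynaptic list turned to -0.27 and the channel list to -0.04 with the authors' normalized values, and each left the outer 2.5% in 8 of 17 alternatives. The interneuron list turned to -0.65 in the second number run. In the first number run alone, the CA3 and mossy cell list had percentile 52.4, the progenitor list 11.3 and the glutamatergic list 88.9. Of the other lists, interferon genes (1.32, percentile 97.4) and oligodendrocyte markers (0.93, percentile 97.2) lay farthest out.

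By the summed CPM of both marker lists, 2 of 47 EGFP GC, 10 of 51 Ascl4 GC, 0 of 46 EGFP CA1 and 3 of 45 Ascl4 CA1 cells had the larger sum on the side of the other cell type. By the number of detected marker genes the counts were 2, 1, 0 and 4. No cell was moved or left out.

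The comparison of Ascl4 with EGFP granule cells asked how granule cells with the Ascl4 virus differ from controls. Genes of the interferon response stood far higher with Ascl4. Ifit1, an interferon-induced blocker of viral RNA translation, was at 163.7 CPM (162.3 to 165.2) in Ascl4 and 0.41 CPM (0.33 to 0.50) in EGFP granule cells, and reached 10 CPM in 11 of 51 and 0 of 47 cells. Irf7, which drives interferon genes, was at 35.5 CPM against 0.24 CPM, in 12 of 51 and 0 of 47 cells. Ifit3, on chromosome 19 from 34583531 to 34588731, had the highest log2 ratio by the naming rule at 6.96, and its ratio of mean CPM was 5.93 without the highest cell in place of 6.76. Cd74, the invariant chain of MHC class II, was at 72.7 against 0.13 CPM, and reached 10 CPM in 8 of 51 and 0 of 47 cells. Without the highest cell its ratio of mean CPM was 5.47 in place of 6.05. The MHC class I genes H2-D1 and B2m, picked after their values were seen, stood at 345 and 189.6 CPM against 7.21 and 12.9 CPM.

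In the other direction, Smoc2 was at 0.11 CPM in Ascl4 and 121.9 CPM in EGFP granule cells (log2 ratio -6.79), and Cxcl12 at 0.17 against 128.3 CPM (-6.78). Each reached 10 CPM in 16 of 47 EGFP and 0 of 51 Ascl4 granule cells, an upper limit of 6.98% in the latter. Both are genes that also set granule cells apart from CA1 cells. The serotonin receptor gene Htr1a (-5.11), the cell cycle kinase gene Cdk6 (-5.12) and the prohormone convertase gene Pcsk1 (-5.23) were lower as well. Without the highest cell the ratio of mean CPM was -4.31 for Cdk6 in place of -5.18. Slc17a7, the vesicular glutamate transporter of these neurons, was at 79.9 CPM (78.9 to 80.97) with Ascl4 and 318 CPM (315 to 320) without, and reached 10 CPM in 26 of 51 and 38 of 47 cells. Prox1 (156.2 against 175.3 CPM) and Calb1 (1201 against 1025 CPM) differed by less than 1.5-fold, while C1ql2, picked after its values were seen, was at 294 against 1017 CPM.

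Among the other genes named by the rule in granule cells, several rested on few cells. The log2 ratio of summed reads was 6.62 for Zscan12, 6.36 for Smurf1, 6.27 for Rhbdd1, 6.09 for Dnph1, 5.89 for Xaf1, 6.91 for Rpap1, 6.59 for Dusp26 and 6.30 for Cxcl13, a chemokine gene. The ratio of mean CPM, over all cells and then without the highest cell, was 5.39 and 3.14 for Zscan12, 5.13 and 2.78 for Smurf1, 5.73 and 3.73 for Rhbdd1, 5.496 and 3.01 for Dnph1 and 5.43 and 3.60 for Xaf1. It was 5.98 and 5.0 for Rpap1, 5.71 and 4.89 for Dusp26 and 6.08 and 4.82 for Cxcl13. Among the lower genes it was -5.52 and -1.35 for Ccdc62, -5.17 and -2.71 for Syna, -5.63 and -4.86 for Psrc1 and -5.44 and -4.74 for Arsj. Bcas1, a gene of oligodendrocytes, had a ratio of summed reads of 6.46 and, without the cells of more than 12000 genes, 0.71. Tekt5 (-6.23), Chst15 (-5.69) and Lct (-5.59) completed the rule's lower genes.

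Interferon and innate immune genes had a median log2 ratio of 4.01 in granule cells, all 22 expressed members were at least 1.5-fold higher, and the medians were 5.68 and 3.03 in the 2 number runs. Since a gene counted as expressed through either group, members high in Ascl4 cells alone were included, and the median without an expression filter was 2.27. Microglia markers were higher alongside them (1.12, percentile 100, 14 of 21 members higher and 1 lower), with medians of 5.24 and 0.70 in the 2 number runs. Members varied, with Cx3cr1, the fractalkine receptor of microglia, at 11.9 against 0.20 CPM, and the growth factor receptor Csf1r, picked after its values were seen, at 53.1 against 79.5 CPM. The log2 ratio of Csf1r was 0.97 and -0.20 in the 2 number runs, and its ratio of mean CPM was -0.28 without the highest cell in place of -1.40. At least 3 interferon-list genes reached 10 CPM in 35 of 51 Ascl4 and 2 of 47 EGFP granule cells. Oligodendrocyte markers (1.31, percentile 99.9) were higher, but stood at -1.33 (percentile 0.09) without the cells of more than 12000 genes, and left the outer 2.5% with the authors' normalized values. Interneuron markers were higher (1.14, percentile 99.7, 7 of 9 members), among them the neuropeptide gene Cck at 696 against 315 CPM. Their percentile was 92.2 without an expression filter and 92.5 in the first number run. The median of activity-regulated genes was lower (-0.32, percentile 1.46), with 14 of 36 members lower, 5 higher and 17 between, and it left the outer 2.5% in 6 of 17 alternatives. Of the immediate early genes picked after their values were seen, Arc (-0.65) was lower, while Junb (-0.27), Fos (-0.12), Egr1 (-0.06) and Npas4 (0.15) differed by less than 1.5-fold, the last 3 with opposite signs in the 2 number runs. Granule cell markers (-0.30, percentile 7.83), CA1 markers (-0.44, percentile 6.5), CA3 and mossy cell markers (0.14, percentile 65.7), immature neuron genes (-0.43, percentile 10.2) and progenitor genes (-0.83, percentile 8.14) did not stand out.

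Nor did lists tied to wiring in granule cells. Trans-synaptic organizers had a median of -0.15 (percentile 27.4), cadherins -0.07 (52.0), immunoglobulin adhesion genes -0.11 (37.9), axon guidance genes 0.09 (79.5), presynaptic release genes 0.16 (96.3) and axon growth genes 0.01 (75.2). Within them Ephb1, a receptor of axon guidance, was at 2.44 against 68.04 CPM (the ratio of mean CPM was -3.43 without the highest cell, in place of -4.33) and the catenin gene Ctnna1 at 55.4 against 1.27 CPM. Proneural and Notch pathway genes had -0.21 (percentile 32.5), glutamatergic and postsynaptic genes 0.04 (74.7), voltage-gated channel genes -0.21 (22.6), GABA receptor genes -0.01 (62.7), p53 and cell death genes 0.17 (74), heat shock genes -0.13 (34.4), astrocyte markers -0.12 (38.2) and oxidative phosphorylation genes 0.13 (94.9). The endothelial list had 4 expressed members, too few for a median. In 1 number run alone some of these lists lay in the outer 2.5%, presynaptic release genes in the first (0.42, percentile 97.85) and oxidative phosphorylation genes (0.13, percentile 98.94) and granule cell markers (-0.72, percentile 0.95) in the second. Over 9783 expressed genes the SD of the log2 ratios was 1.39 for all cells, and 2.34 and 1.60 for the 2 number runs taken alone. Between the 2 number runs it was 2.08 inside EGFP and 1.74 inside Ascl4 granule cells. These SDs rest on different numbers of cells and are not a test. The ratios of the 2 runs had a Pearson r of 0.124 and a Spearman rho of 0.107 across genes, which are not independent replicates.

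**Figure D2:**
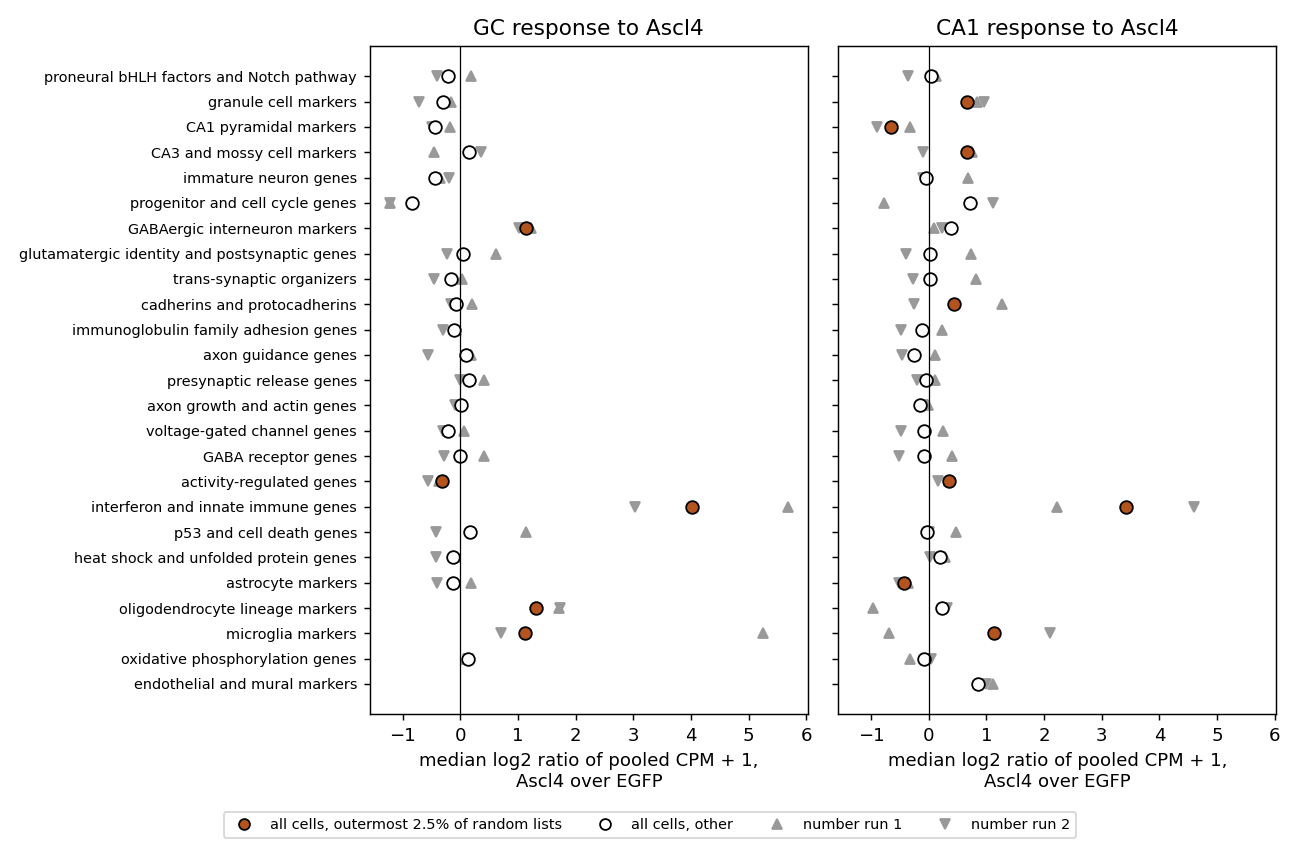
Median log2 ratio of pooled CPM plus 1, Ascl4 over EGFP, of each gene list in granule cells and in CA1 cells, for all cells (circles, filled where the list lay in the outermost 2.5% of random lists) and each number run (triangles). Interferon genes had medians of 4.01 in GC and 3.43 in CA1 cells.

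The comparison of Ascl4 with EGFP CA1 cells asked the same of pyramidal neurons. Interferon genes again stood far higher with Ascl4. Single genes of antigen presentation did too, of which MHC class I genes such as H2-K1 are on the interferon list. No list was set for MHC class II genes. The T-cell chemokine gene Ccl5, on chromosome 11, had the highest log2 ratio by the naming rule at 7.44, with 192.3 CPM (190.5 to 194.2) in Ascl4 and 0.11 CPM (0.07 to 0.16) in EGFP CA1 cells. It reached 10 CPM in 13 of 45 and 0 of 46 cells, and the ratio of mean CPM was 6.25 without the highest cell, in place of 7.06. H2-K1, an MHC class I gene, was at 205.3 against 0.84 CPM, and Cd74 at 265 against 2.79 CPM, in 13 of 45 and 1 of 46 cells. Without the highest cell the ratio of mean CPM of Cd74 was 6.92 in place of 5.87. Ifi27l2a, an interferon-induced mitochondrial protein gene, reached 10 CPM in 19 of 45 Ascl4 and 0 of 46 EGFP CA1 cells. Oasl2 (5.81), Trp53i11 (5.78), Lgals3bp (7.04), Pld4 (6.5), H2-Aa (6.32) and H2-Ab1 (6.31) were higher too. Without the highest cell the ratio of mean CPM was 5.32 in place of 6.61 for Lgals3bp, 5.49 in place of 6.55 for H2-Aa and 5.31 in place of 6.28 for H2-Ab1. H2-Aa reached 10 CPM in 5 and H2-Ab1 in 4 of 45 Ascl4 CA1 cells. Cxcl13 and Il1rn rested on few cells, with 4.20 in place of 6.83 and 1.00 in place of 6.02.

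Several CA1 marker genes, though not all, were lower in Ascl4 CA1 cells. Neurod6 was at 94.2 CPM (92.9 to 95.5) with Ascl4 and 319 CPM (317 to 322) without, and reached 10 CPM in 19 of 45 and 40 of 46 cells. Fibcd1 was at 165.4 against 543 CPM, in 16 of 45 and 39 of 46 cells, with log2 ratios of -0.61 and -3.23 in the 2 number runs, and -2.68 in the mean of per-cell CPM in place of -1.71. Wfs1, another CA1 marker, was higher (246 against 78.2 CPM), and so was Dcn (607 against 174.8 CPM). The log2 ratio of Wfs1 was 1.64, and 0.70 in the mean of per-cell CPM. Of other pyramidal genes, picked after their values were seen, Cpne7 was at 1223 against 1257 CPM, Mpped1 at 509 against 647 CPM and Sv2b at 499.7 against 331 CPM. The log2 ratio of Sv2b was 0.59, but 0.08 in the mean of per-cell CPM, and it turned from 1.37 to -0.42 between the 2 number runs, as that of Cpne7 did from 0.705 to -0.43. Slc17a7 was at 294 against 533 CPM and Calb1 at 1104 against 617 CPM. The lowest genes by the naming rule included the TNF receptor gene Tnfrsf19, at 0.18 against 43.2 CPM, the dopamine receptor gene Drd5 (-4.32) and the adenylyl cyclase gene Adcy8 (-4.52). The others were Lims2 (-4.86), Trmt13 (-4.77), Lyrm9 (-4.47), Hs3st1 (-4.32) and Ccdc51 (-4.32). Armt1 (-5.29), Pdcd2 (-4.45), Lrrc39 (-4.42) and Kdm8 (-4.37) were lower too. In the mean of per-cell CPM Armt1 stood at -3.78, and at -2.99 without the highest cell, Lims2 at -5.70 and -4.67, and Kdm8 at -3.76.

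Interferon and innate immune genes had a median log2 ratio of 3.43 in CA1 cells, with 19 of 21 members higher and 0 lower, and 2.22 and 4.60 in the 2 number runs. Without an expression filter the median was 3.15. Microglia markers were higher (1.13, percentile 100, 17 of 23 members higher), with the chemokine gene Ccl3 at 513 against 32.3 CPM. In the first number run the microglia list was lower (-0.68, percentile 0.19) while the interferon list was higher, and with all cells of the unfiltered table it left the outer 2.5%. At least 3 interferon-list genes reached 10 CPM in 34 of 45 Ascl4 and 16 of 46 EGFP CA1 cells. CA1 pyramidal markers were lower (-0.65, percentile 0.01, 13 of 25 members lower and 2 higher), a call kept in 16 of 17 alternatives. The alternative that lost it was the first number run (-0.32, percentile 4.68), against -0.90 (percentile 0.00) in the second. Granule cell markers were higher (0.67, percentile 98.9, 7 of 13 members higher and 2 lower), with the guanine exchange factor gene Dock10 at 37.9 against 0.25 CPM (log2 ratio 4.96). Its ratio of mean CPM was 4.29, and 3.34 without the highest cell. The call for this list was kept in 13 of 17 alternatives. Only 13 of its 29 genes passed the expression filter, some through the Ascl4 group alone, and without the filter the median was 0.19 at percentile 85.7, outside the outer 2.5%. CA3 and mossy cell markers (0.67, percentile 99.6) and cadherins (0.44, percentile 97.7) were higher, but at -0.09 and -0.25 in the second number run. The median of activity-regulated genes was higher (0.36, percentile 99.8), with 7 of 35 members higher, 4 lower and 24 between, and in neither number run alone did the list reach the outer 2.5%. Of the immediate early genes picked after their values were seen, Arc (-1.14), Junb (-0.33) and Npas4 (-0.16) had log2 ratios below 0 and Fos (0.51) and Egr1 (0.37) above 0, Fos with -0.31 in the first number run. Astrocyte markers were lower (-0.43, percentile 1.96), a call kept in 11 of 17.

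The other lists did not stand out in CA1 cells in the summed reads, but some did in 1 number run. Trans-synaptic organizers had a median of 0.03 (percentile 64.6), immunoglobulin adhesion genes -0.11 (28.6), axon guidance genes -0.25 (8.53), presynaptic release genes -0.04 (46.9) and axon growth genes -0.16 (9.83). Within them Rph3a, a vesicle protein gene, was at 31.8 against 3.21 CPM, and Pclo, a scaffold gene of the active zone, at 60.7 against 228.2 CPM. Proneural and Notch pathway genes had 0.03 (percentile 62.8), immature neuron genes -0.05 (43.9), progenitor genes 0.72 (92.1), interneuron markers 0.38 (88.98), glutamatergic and postsynaptic genes 0.02 (65.8) and voltage-gated channel genes -0.08 (31.98). GABA receptor genes had -0.09 (percentile 33.9), p53 and cell death genes -0.03 (48.2), heat shock genes 0.20 (96.3), oligodendrocyte markers 0.23 (78.95), endothelial markers 0.86 (96.3) and oxidative phosphorylation genes -0.07 (32.8). In the first and second number run trans-synaptic organizers had 0.83 (percentile 99.97) and -0.27, glutamatergic and postsynaptic genes 0.73 (99.89) and -0.39, oligodendrocyte markers -0.97 (2.11) and 0.32, and oxidative phosphorylation genes -0.32 (1.01) and 0.04. Immunoglobulin adhesion genes had 0.24 and -0.47 (percentile 0.97), voltage-gated channel genes 0.25 and -0.49 (0.51), and GABA receptor genes 0.40 and -0.51 (2.47). Over 9781 expressed genes the SD of the log2 ratios was 1.12 for all cells, and 1.98 and 1.34 for the 2 number runs taken alone. Between the 2 number runs it was 1.71 inside EGFP and 1.56 inside Ascl4 CA1 cells, again over different numbers of cells. The ratios of the 2 runs had a Pearson r of 0.074 and a Spearman rho of 0.053 across genes.

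**Figure D3:**
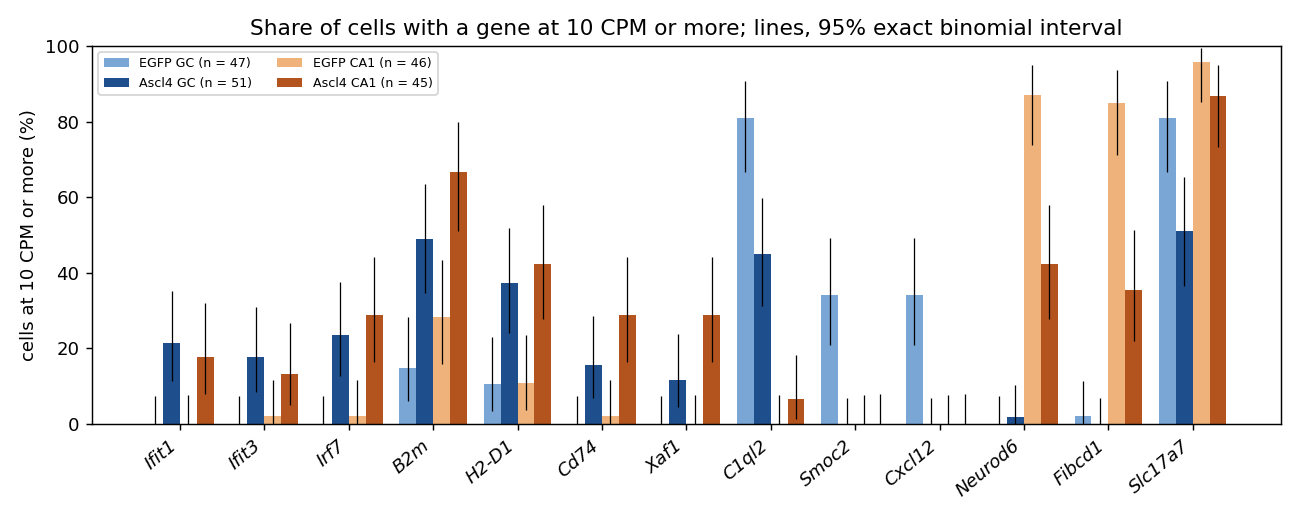
Share of cells in which a gene reached 10 CPM (percent, bars) in the 4 groups, with 95% exact binomial intervals as lines; the genes were picked after their values were seen. Ifit1 reached 10 CPM in 21.6% of Ascl4 GC cells and 0 of 47 EGFP GC cells, and Neurod6 in 86.96% of EGFP and 42.2% of Ascl4 CA1 cells.

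Setting both responses side by side asked how far the differences between Ascl4 and EGFP cells were alike in the 2 neuron types. Across 8865 genes expressed in both comparisons, the log2 ratios in GC and CA1 cells had a Pearson r of 0.133 and a Spearman rho of 0.076. Genes are not independent replicates. Without the interferon and microglia lists r was 0.101, and r was 0.025 between the first and 0.116 between the second number runs. Between the 2 number runs of the same cell type r was no higher, 0.124 in GC and 0.074 in CA1 cells. The low r between cell types therefore cannot tell different responses from poor repeatability. The 10 genes with the largest shared differences were Cxcl13, Cd74, Xaf1, Ifit3, Ifit1, Rtp4, Oasl2, Irf7, Lgals3bp and H2-Aa, all higher with Ascl4. Xaf1 and Rtp4, interferon-induced genes, stood at 61.9 and 57.2 CPM in Ascl4 GC cells and at 55.8 and 28.8 CPM in Ascl4 CA1 cells, and below 0.1 CPM in both EGFP groups. Without the highest cell the ratio of mean CPM of Rtp4 was 4.50 in place of 5.23 in CA1 cells, and that of Xaf1 3.60 in place of 5.43 in GC cells. Of 304 genes that met the naming rule's size criteria in both responses, 64.8% differed in the same direction and 35.2% in opposite directions, which are not counts of changed genes.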

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

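The tests of explanations in this part were chosen after the result they bear on had been seen, while the lists and main alternatives were set before. Opposite directions in the 2 responses were found for 1 called list and for 1 of the highest and lowest genes named by the rule, and the difference between the responses was not tested. Of all 304 genes that met the rule's size criteria in both responses, 35.2% differed in opposite directions, so such a gene is not rare. Activity-regulated genes had a median log2 ratio of -0.32 in GC and 0.36 in CA1 cells, with the same signs in both number runs. The GC list left the outer 2.5% of random lists in 6 of 17 alternatives, and the CA1 list did so in each number run alone. Pcsk1, which encodes a prohormone convertase, had -5.23 in GC cells (0.89 against 69.96 CPM) and 2.73 in CA1 cells (89.7 against 12.7 CPM). It rested on few cells, reaching 10 CPM in 1 Ascl4 GC, 6 EGFP GC, 11 Ascl4 CA1 and 5 EGFP CA1 cells. The 39 cells outside the quality-controlled table, which entered the comparisons only in the alternative with all cells, also held Ascl4. Its level there was 15380 CPM in 5 Ascl4 GC cells and 13588 CPM in 13 Ascl4 CA1 cells, against 87.8 CPM in 13 EGFP GC and 20.9 CPM in 8 EGFP CA1 cells. It reached 200 CPM in 5 of 5 Ascl4 GC and 12 of 13 Ascl4 CA1 cells, but also in 4 of 13 EGFP GC and 1 of 8 EGFP CA1 cells, with a highest value of 674.3 CPM in an EGFP GC cell.

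Interferon genes and several MHC genes, some of them on the interferon list, were higher in Ascl4 cells of both types, alongside microglia markers in the summed reads. In the first number run of CA1 cells, microglia-list CPM was instead lower with Ascl4, at 3306 against 4494. Interferon-list CPM in that run was higher, at 986.5 against 370.1. More microglial RNA of the make-up seen in EGFP cells would leave the ratio of interferon-list to microglia-list CPM as it was, but this ratio was higher by a log2 value of 2.36 in GC and 1.46 in CA1 cells, and above 0 in every number run (1.30 and 2.22 in GC, 1.86 and 0.85 in CA1). RNA of activated microglia taken up with the neuron stays open as a candidate source, since of the Ascl4 cells with at least 3 interferon-list genes at 10 CPM, only 7 of 35 GC and 1 of 34 CA1 cells lacked a microglia-list gene. Among Ascl4 cells with fewer interferon-list genes, 10 of 16 GC and 1 of 11 CA1 cells lacked a microglia-list gene. The CA1 counts cannot decide, since 43 of 46 EGFP CA1 cells had such a gene as well. In GC, where 26 of 47 EGFP cells had one, both lists went together. No adjustment was made for the number of genes that a cell showed at 10 CPM. An innate response of the neurons to Ascl4, or to a second virus, is open as well and was not tested, since no group received a second virus without Ascl4.

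The median of CA1 markers was lower in Ascl4 CA1 cells, with 13 of 25 members lower and 2 higher. In the 2 number runs this median was -0.32 (percentile 4.68) and -0.90 (percentile 0.00). Reads taken up by the Ascl4 transcript amount to 0.939% of all reads, against the 36.2% that the median of -0.65 would need. Granule cells among the cells labelled CA1 would bring their abundant genes, but 16 granule cell genes nearly absent from EGFP CA1 cells reached a median of 1.31% of their EGFP GC level, C1ql2 1.98% and the highest, Cald1, 33.7%. Ascl4 GC cells would be the closer reference. There 10 of 27 expressed granule cell markers were lower and 6 higher, with C1ql2 at 294 against 1017 CPM, so some percents are too low. By summed marker CPM, 3 of 45 Ascl4 CA1 and 0 of 46 EGFP CA1 cells went against their label. A small share of granule cells thus stays open. RNA of other cells that lowers all neuronal genes alike would lower other neuronal lists as much. Medians were -0.04 for presynaptic genes, 0.02 for glutamatergic and postsynaptic genes and -0.08 for voltage-gated channel genes, against -0.65. Axon guidance genes were the lowest of the neuronal lists besides CA1 markers, at -0.25. In the second number run presynaptic genes had -0.20, glutamatergic genes -0.39 and channel genes -0.49, against -0.90 for CA1 markers. In the first they had 0.12, 0.73 and 0.25, against -0.32. The medians stood above that of CA1 markers in both runs, but they moved between runs. Single presynaptic genes also spread widely (SD 0.838). These medians therefore cannot decide whether such RNA is the source of the difference or of a part of it. A lower level of CA1 identity genes caused by Ascl4 is a biological explanation that was not tested.

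Ascl4 reads occurred in every EGFP cell. Expression of the cells' own gene stays open: of genes at 20 to 100 CPM 99.63% were read in a smaller share of EGFP GC cells and 99.81% in a smaller share of EGFP CA1 cells, but a share of all cells is the ceiling of this measure and the starting observation, and 18 and 9 other genes reached it too. Reads carried over between libraries are a candidate source that stays open as well. EGFP cells held 0.335% (GC) and 0.346% (CA1) of the Ascl4 level of Ascl4 cells, while 7 genes confined to 1 cell type had a median of 0.074% of their level in the other type, which neither matches nor rules out carry-over. These 7 genes were picked as confined to 1 type, so low values follow in part from the choice. They also set GC against CA1 libraries, not EGFP against Ascl4 libraries of 1 type. Viral spread or transcripts of the second virus in EGFP cells were not tested.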

How the results depend on the processing

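Leaving out cells with more than 12000 genes, leaving CT010467.1 and Ascl4 out of totals, and leaving the interferon and microglia lists out of the similarity were chosen after seeing the data. The interferon list stayed in the outer 2.5% in both responses under all 17 alternatives, as did granule cell and CA1 markers between EGFP CA1 and GC cells. Microglia markers did so in the GC response, and in the CA1 response they kept the call in 15 of 17. Of 1230 alternative values for genes named by the rule, 932 moved by less than the SD between the values of the number runs, 298 moved more and 0 changed sign, which the rule itself ensured for the mean of per-cell CPM and both runs. For other genes 4615 of 5340 values moved by less, and 82 of 356 genes changed sign under at least 1 alternative. For lists 1021 of 1236 values moved by less, 47 of 73 lists changed sign under at least 1 alternative, and 8 values of called lists did. This SD is wide where the runs differ, so a sign change can lie within it. The cause was not tested for any of the values that follow, apart from smaller log2 ratios under a larger pseudocount, which follow from its construction.

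With the mean of per-cell CPM, Ascl4 was at 13330 CPM in Ascl4 GC and 8684 CPM in Ascl4 CA1 cells, and granule cell markers in CA1 had a median of 1.14. In the first number run alone the SD of the log2 ratios was 2.34 in GC, 1.98 in CA1 and 2.59 between EGFP CA1 and GC cells, and the similarity r was 0.025. Microglia markers there had 5.24 in GC, 6.16 between EGFP CA1 and GC, and the reversed value of -0.68 in CA1, and granule cell markers in CA1 had 0.83. In the second number run alone CA3 and mossy cell markers (-0.095) and cadherins (-0.255) reversed in CA1, and interneuron markers reversed between EGFP CA1 and GC (-0.65). Activity-regulated genes had -0.56 in GC and 0.16 in CA1, and granule cell markers 0.96 in CA1 and -4.38 between EGFP CA1 and GC.

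Without the deepest 10% of cells activity-regulated genes in GC had -0.15, and granule cell markers 1.27 in CA1 and -4.40 between EGFP CA1 and GC. In the mean of per-cell CPM without the highest cell per gene granule cell markers in CA1 had 1.11, against 1.14 in that mean over all cells. CA1 markers between EGFP CA1 and GC had 2.69, against 2.44 in that mean over all cells. Without cells over 12000 genes oligodendrocyte markers in GC reversed to -1.33. With a pseudocount of 10 CPM interferon genes in GC had 2.10, and granule cell markers 0.36 in CA1 and -2.41 between EGFP CA1 and GC, the latter -6.89 with 0.1 CPM. With no expression filter granule cell markers had 0.19 in CA1 and -4.125 between EGFP CA1 and GC. With the stricter filter they had 0.445 and -4.49, CA1 markers had 2.56 between EGFP CA1 and GC, and CA3 and mossy cell markers in CA1 reversed to -0.076.

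With the authors' normalized values granule cell markers had 1.17 in CA1 and -6.35 between EGFP CA1 and GC, where presynaptic (-0.265) and voltage-gated channel genes (-0.039) reversed. In thinned cells granule cell markers had 1.16 in CA1 and -4.17 between EGFP CA1 and GC, and 41 EGFP CA1 cells had an Ascl4 read. With all cells granule cell markers between EGFP CA1 and GC had -4.52, and the median of detected genes in Ascl4 CA1 cells was 6200. With at least 5 reads per gene the medians were 3689, 3745, 3976 and 4475 genes in EGFP GC, Ascl4 GC, EGFP CA1 and Ascl4 CA1 cells. By the number of detected list genes 1 Ascl4 GC cell went against its label. No pairing of single cells was possible because the title numbers are not shared between groups. Comparisons in each number run alone set the first, or the second, runs of the groups against each other. These hold different title numbers and are not known to share a batch.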

Other observations

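MHC class II genes, which neurons rarely express, were among the genes higher with Ascl4 in both cell types, with H2-Aa at 19.5 against 0.04 CPM in GC and 81.7 against 0.03 CPM in CA1 cells. It reached 10 CPM in few cells, 6 of 51 Ascl4 GC and 5 of 45 Ascl4 CA1 cells, and without the highest cell its log2 ratio of mean CPM was 3.52 in place of 4.20 in GC and 5.49 in place of 6.55 in CA1 cells. The neurofilament gene Nefl, picked after its values were seen, was lower with Ascl4 in both types, at 306 against 1016 CPM in GC and 269.6 against 532 CPM in CA1 cells. Snap25, a synaptic vesicle fusion gene picked in the same way, was at 3446 against 3145 CPM in GC and 3520 against 3620 CPM in CA1 cells.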
